A study of Mus musculus with 5 samples.

How the data were processed

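RNA was measured in 5 mammary tumours of SV40-transgenic mice of the FVB background at 20 weeks of age. Per the labels' protocols, dams received a control diet or a diet with 26% broccoli sprouts (BSp) from conception to weaning, and the offspring themselves were not treated. The labels give 2 control tumours and 3 tumours of offspring of BSp-fed dams, called maternal BSp here. Total RNA with an integrity number of at least 7.0 went into a strand-specific mRNA library kit, per the labels' protocols. Samples were grouped and numbered by their description field. That the libraries of a group came from separate animals is not stated in so many words, so p-values measure the spread between these libraries.

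The normalised table holds, per the file headers, 1 column of normalised values for each library, a coverage signal of reads per gene in 38918 features. Per the submitters' processing notes, FastQC, Trim Galore, cutadapt, STAR and DESeq were used with the mouse builds GRCm38 and mm10. No versions are given there, and the counting tool, gene annotation and strand setting are not given in the sources used here. In the deposited signal each column sums to 1106813, the total of control replicate 1. All values above 0 were whole multiples of the value of 1 read, within 0.1 read, so whole reads were recovered for 100% of them. Recovered totals were 1106813 and 3909583 reads in control replicates 1 and 2, and 8459029, 61663199 and 13796272 reads in maternal BSp replicates 1, 2 and 3, a 55.7-fold range in which both controls lay below every maternal BSp library. The value of 3 reads, the upper limit that a count of 0 allows, was 3 in control replicate 1, 0.849 in control replicate 2 and 0.0538 in maternal BSp replicate 2. Such limits cover counting error only. The second deposited table lists 2447 genes with the authors' group means, fold ratios, unadjusted p-values and analysis-of-variance statistics, per the file headers. Those p-values follow from 5 residual degrees of freedom, and with 2 degrees of freedom for the groups this corresponds to 8 libraries in 3 groups. The third group is not analysed here. In 6 rows the identifier is a calendar date in place of a gene symbol.

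The design had been fixed for either counts or normalised values before the data were examined. As the table holds normalised values, genes changed were tested with limma 3.58.1 (trend, no covariate) in R 4.3.3 on log2(value + 1) for the 9870 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of low genes. The 39 gene lists, with 701 entries, were fixed before the data were examined. The 30 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided, adjusted over those lists. Camera with an estimated correlation and fry were alternatives. Fry tests whether the genes of a list move one way on balance, against no change, where camera compares them with all other genes. Closeness of the libraries was tested by an exact permutation over the 10 ways to choose 2 of 5 libraries. The genes named follow a rule written before the data were examined. Up to 12 genes per direction pass the threshold, have a mean of at least 100 and have every maternal BSp library beyond both controls. As no gene passed the threshold, the places were filled by smallest unadjusted p under the same other conditions. The rule adds 27 fixed genes, the 3 members of each list with the smallest p, and 4 members of each called list. Some genes that these rules name are not reported here. Genes outside that rule were chosen after their values were seen and are named as such. Gene models without a common symbol were left out of the first part. Gene positions come from GENCODE M21 on GRCm38, which names 35529 of the 38918 features. Strand use in the counting is not given, so genes that overlap on opposite strands, and genes with near-identical copies such as ribosomal protein genes and their pseudogenes, are uncertain.

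The steps were tested on simulated data, with counts drawn for the 9870 genes from the means and totals of these libraries, 200 genes changed, and 3 libraries against 2. With the dispersion estimated from these libraries, limma recovered 4.41% of genes changed by 1 on the log2 scale, 23.4% of those changed by 2 and 69.1% of those changed by 3. Of its 78 calls, 13 were false (16.7%), above the nominal 5%. At a dispersion of 0.01 it recovered 94.8%, 100% and 100%.

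Alternatives fixed before the data were examined were other filters, pseudocounts of 0.5 and 5, other scalings, each library left out in turn, a replicate block, array weights, a robust prior, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. DESeq2 was run with its default independent filtering. Its counts with that filtering set for 0.05 and with none are also given, since the setting changes the count. Alternatives chosen after seeing the data were reads thinned to 1106813 per library, removal of a trend in transcript length and GC content per library (loess, span 0.3, for the 9356 genes with both values, 94.8% of those tested), totals without mitochondrial and rRNA-like genes, and leaving out the 2 libraries with salivary gene reads. All libraries were used, and no sample column was left out. Summaries and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.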

Results

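Gene expression was measured by RNA sequencing in 5 mammary tumours of mice of a line that carries an SV40 transgene on the FVB background. The series asks whether broccoli sprouts in the diet of the dam leave a trace in tumours of her offspring. Broccoli sprouts (BSp) are a source of sulforaphane, which is known to activate the transcription factor NRF2 and to inhibit histone deacetylases. Dams ate a control diet or a diet with 26% BSp from conception to weaning, and tumours were taken from untreated offspring at 20 weeks. There were 2 control and 3 maternal BSp libraries. Depth was uneven, with 1106813 reads in control replicate 1, 3909583 in control replicate 2, and 8459029, 61663199 and 13796272 in maternal BSp replicates 1, 2 and 3, so that both controls were shallower than every maternal BSp library. Values are reads per gene scaled by the authors to 1 common total, given as mean ± SD with n = 2 control and n = 3 maternal BSp libraries.

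**Figure D1:**
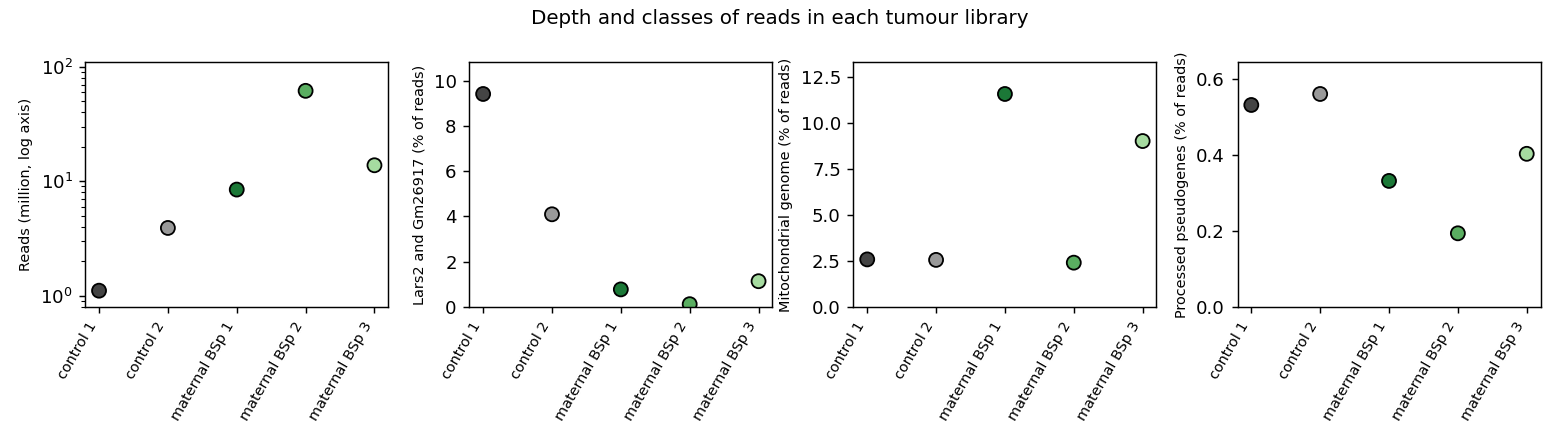
Reads per library (log axis) and the percent of reads from Lars2 and Gm26917, from the mitochondrial genome and from processed pseudogenes. Each point is 1 library. The rRNA-like genes Lars2 and Gm26917 took 9.40% and 4.09% of reads in the controls and 0.117% to 1.13% in maternal BSp.

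The classes of reads differed between the groups. Lars2, which holds an rRNA-like stretch, and the non-coding Gm26917 took 9.40% and 4.09% of reads in the controls against 0.770%, 0.117% and 1.13% in maternal BSp replicates 1, 2 and 3. Processed pseudogenes took 0.531% and 0.560% of reads in the controls and 0.332%, 0.194% and 0.403% in maternal BSp. Mitochondrial transcripts took 2.58% and 2.56% in the controls and 2.41% in maternal BSp replicate 2, but 11.6% and 9.03% in maternal BSp replicates 1 and 3. Short transcripts were higher in the controls: the median log2 fold change of maternal BSp over control was -0.41 in the decile of shortest transcripts (937 genes) and 0.44 in that of the longest (935 genes). It was 0.53 in the decile of lowest GC content and -0.07 in that of the highest. The controls correlated with each other at r = 0.912 and the maternal BSp libraries among themselves at 0.712 to 0.822. Libraries of different groups correlated at 0.757 to 0.833. All these are across genes, which are not independent replicates. Whether libraries of 1 group were closer to each other than to the other group gave p = 0.6 in a one-sided exact permutation test, which cannot go below 0.1 here.

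The genes with the smallest unadjusted p and a mean of at least 100 included Atp1b1, a subunit of the sodium pump, and Gclm, a subunit of the enzyme that limits glutathione synthesis, both higher in maternal BSp, and the mitochondrial Glrx5 and the iron-binding secretory protein Ltf, both lower. No gene passed the test: limma called 0 of 9870 genes, with a smallest adjusted p of 0.407. At an unadjusted p under 0.05 there were 1101 genes, 791 higher and 310 lower in maternal BSp. The edgeR quasi-likelihood test called 0 genes as well, with 971 at an unadjusted p under 0.05, while DESeq2 called 87, of which 28 were higher and 59 lower, and limma with array weights called 422 higher and 277 lower. The array weights were 1.48 for each control and 2.97, 0.34 and 0.46 for maternal BSp replicates 1, 2 and 3. The calls with array weights thus lean on maternal BSp replicate 1. The values of maternal BSp and control libraries did not overlap for 3257 genes (33.0%), 2348 higher and 909 lower in maternal BSp. Averaged over all possible splits of the libraries the share is 20%. How far a single split can depart from that average was not tested, and the count was made on the deposited scale only. The direction of the whole set depended on the scaling. The median log2 fold change of all tested genes was 0.21 as deposited, -0.01 with upper quartile scaling and 0.03 with median-of-ratios or quantile scaling, and the share of genes at p under 0.05 that were higher was 71.8% as deposited and 40.2%, 47.9% and 47.1% with these scalings.

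Named by smallest unadjusted p, the 12 genes higher in maternal BSp were Atp1b1, mt-Atp8, Ccnl1, Gclm, Xist, Picalm, Arrdc3, Ogt, Fnbp1l, Fgfr1, Neat1 and Gnas. None passed the adjusted threshold (limma adjusted p 0.407 for each). Each kept its direction under every alternative tried, but the rule took only genes whose groups do not overlap. That largely fixed the direction in advance, so it is no sign of robustness. Atp1b1 (chromosome 1, 164437109 to 164458355) measured 26.7 ± 6.66 in control and 190 ± 86.6 in maternal BSp, a log2 fold change of 2.70 (SE 0.46). Gclm (chromosome 3, 122245557 to 122270732) measured 79.1 ± 29.9 and 311 ± 108, with a log2 fold change of 1.96 (SE 0.42). The nuclear non-coding RNAs Xist and Neat1 had log2 fold changes of 2.72 (SE 0.63) and 2.29 (SE 0.57). Fgfr1, a growth factor receptor, measured 72.5 ± 41.7 and 309 ± 146, and Gnas, the stimulatory G protein subunit, 221 ± 59.4 and 738 ± 249. Arrdc3 was tight within each group, at 66.3 ± 7.51 and 170 ± 9.46. Ccnl1, Picalm, Ogt and Fnbp1l had log2 fold changes between 1.40 and 1.75.

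The 12 genes lower in maternal BSp were Glrx5, Ltf, Sfn, Crip1, Med28, Fis1, Chchd2, Rpl36al, Dgcr6, Lars2, Clta and Csrp2, again with none passing. Ltf (chromosome 9, 111019271 to 111042767) measured 320 ± 55.7 in control and 38.8 ± 23.2 in maternal BSp, a log2 fold change of -3.26 (SE 0.62). Sfn measured 421 ± 13.2 and 90.7 ± 78.2. Glrx5, a mitochondrial iron-sulfur cluster protein (chromosome 12, 105032688 to 105042906), measured 181 ± 53.4 and 47.8 ± 5.45. The mitochondrial proteins Chchd2 and Fis1 had log2 fold changes of -1.69 (SE 0.44) and -1.22 (SE 0.32). The rRNA-like Lars2 had the lowest log2 fold change of the 12 genes, at -3.62 (SE 0.97).

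**Figure D2:**
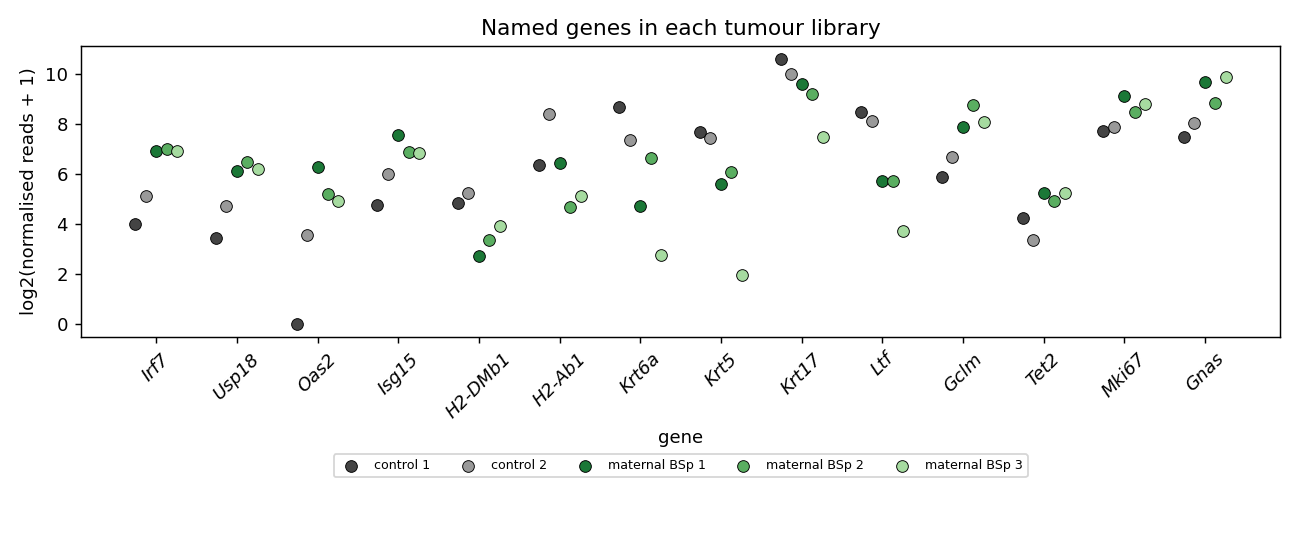
Normalised reads of 14 named genes on a log2(value + 1) axis, with 1 point per library. Irf7 lies at 15 and 34.0 in the controls and at 119 to 128 in maternal BSp, while Krt6a lies at 404 and 163 in the controls and at 5.78 to 98.0 in maternal BSp.

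Genes induced by interferon were higher in maternal BSp as a set. Of 23 tested members 18 were higher and 5 lower, 11 had an unadjusted p under 0.05, all higher, and 5 passed when adjusted over the list alone against 0 over all genes tested. Irf7, the transcription factor that amplifies the response, measured 24.5 ± 13.4 in control and 122 ± 4.87 in maternal BSp. Usp18, which removes the ubiquitin-like ISG15, measured 17.6 ± 10.8 and 76.6 ± 10.7, Isg15 itself 44.3 ± 25.9 and 139 ± 42.03, and the RNA sensor Oas2 5.38 ± 7.61 and 47.4 ± 26.4. The median log2 fold change of the list was 1.14 (camera adjusted p 0.00368, and adjusted p = 0.82 with an estimated correlation). As the median of the members, each against its mean over the 5 libraries, the list lay at -1.20 and 0.0011 in the controls and at 0.63, 0.60 and -0.016 in maternal BSp replicates 1, 2 and 3. Without control replicate 1 the median was 0.54 and the adjusted p = 0.551, and without control replicate 2 the median was 1.72. Over 24 alternatives the adjusted p lay between 4.84e-10 and 0.977.

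Markers of basal and myoepithelial cells were lower in maternal BSp, with 12 of 13 tested members lower. The keratins Krt6a, Krt5 and Krt17 measured 283 ± 171, 188 ± 21.2 and 1279 ± 375 in control and 43.1 ± 48.6, 38.6 ± 32.3 and 515 ± 306 in maternal BSp, while the integrin Itga6 was higher, at 49.9 ± 12.9 and 99.1 ± 25.7. The list's median log2 fold change was -1.02 (camera adjusted p 0.000438). With an estimated correlation the adjusted p = 0.82, and over 24 alternatives it lay between 4.76e-09 and 0.82. The median was -0.65 without control replicate 1 and -0.37 without maternal BSp replicate 3. As the median of the members, each against its mean over the 5 libraries, the list lay at 0.85 and 0.28 in the controls and at 0.23, 0.42 and -1.88 in maternal BSp replicates 1, 2 and 3, so that replicate 2 lay above control replicate 2. Of the keratins, Krt5 was 2.89 in maternal BSp replicate 3 and 47.1 and 65.8 in replicates 1 and 2.

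Antigen presentation genes of dendritic cells and MHC class II were lower, in all 6 tested members of 15. H2-DMb1, which helps load peptides, measured 32.4 ± 6.22 in control and 9.70 ± 4.35 in maternal BSp. H2-Ab1 measured 209 ± 179 and 48.5 ± 33.7, H2-Aa 92.5 ± 74.2 and 29.1 ± 28.4, and H2-DMa 29.2 ± 17.2 and 12.1 ± 2.63. These genes are neighbours on chromosome 17, from 34119541 (H2-DMa) to 34287823 (H2-Aa), so they are not separate signs of a cell type. H2-DMa, H2-DMb1 and H2-Ab1 lie in the window of neighbouring genes that was highest in control replicate 2. H2-Ab1 was 336 in control replicate 2, 82 in control replicate 1 and 87.0 in maternal BSp replicate 1, so the groups overlapped for this gene. The list's median was -1.69 (camera adjusted p 6.62e-05, and adjusted p = 0.82 with an estimated correlation) and without control replicate 2 it was -0.72. By library, on the scale used for the basal list, it lay at 0.09 and 1.63 in the controls and at 0.08, -1.16 and -0.70 in maternal BSp. With no filter on low values the adjusted p was 0.154. Over 23 alternatives it lay between 1.54e-15 and 0.82.

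The remaining called lists concern the ribosome and mitochondria. Cytosolic ribosomal protein genes were lower in 22 of 25 members, with a median of -0.54 (camera adjusted p 6.62e-05, and adjusted p = 0.82 with an estimated correlation). The median was -0.29 without control replicate 2, -0.22 without maternal BSp replicate 2 and -0.92 without maternal BSp replicate 3. Rps14 measured 3751 ± 17.9 and 1690 ± 1075, Rps4x 1997 ± 339 and 975 ± 302, Rpl8 2058 ± 347 and 1123 ± 598, and Rplp0 2715 ± 908 and 1490 ± 262. Nuclear oxidative phosphorylation genes were lower in 17 of 23 members, with a median of -0.26 (adjusted p 0.0041, and adjusted p = 0.82 with an estimated correlation). The median was -0.17 without control replicate 2, -0.15 without maternal BSp replicate 2 and -0.44 without maternal BSp replicate 3. Cox5a measured 603 ± 53.7 and 186 ± 114, Ndufb8 506 ± 95.9 and 240 ± 55.4, and Ndufa4 837 ± 309 and 440 ± 225, while Uqcrc2 was 67.7 ± 23.6 and 123 ± 30.2. Transcripts of the mitochondrial genome were higher in 12 of 13 members, with a median of 1.23 (adjusted p 0.0126, and adjusted p = 0.82 with an estimated correlation). By library, as the median of the members against their means over the 5 libraries, that list lay at -0.74 and -0.74 in the controls and at 1.48, -0.99 and 1.07 in maternal BSp replicates 1, 2 and 3. On this scale the ribosomal list lay at 0.05 and 0.58 in the controls and at -0.21, -0.83 and 0.50 in maternal BSp replicates 1, 2 and 3, so that replicate 3 lay above control replicate 1. The oxidative phosphorylation list lay at 0.04 and 0.28 in the controls and at -0.27, -0.22 and 0.30, highest in maternal BSp replicate 3. For mt-Co1 the libraries read 3992 and 4163 in control and 27120, 8217 and 19200 in maternal BSp, and mt-Cytb read 1552, 1549, 9864, 1506 and 6583. mt-Atp8 and mt-Nd4l had log2 fold changes of 3.19 (SE 0.65) and 1.52 (SE 0.66). Over 24 alternatives the adjusted p lay between 2.11e-10 (ribosomal), 5.37e-06 (oxidative phosphorylation) or 2.18e-11 (mitochondrial) and 0.82. Removing a length and GC trend gave an adjusted p of 0.261 for the ribosomal list and 0.356 for the oxidative phosphorylation list, while the mitochondrial list kept a median of 1.19 with an adjusted p of 0.00011. The mitochondrial list was lost without maternal BSp replicate 1 (median 0.79, adjusted p 0.284) or 3 (0.352), and its median was 1.98 without replicate 2.

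**Figure D3:**
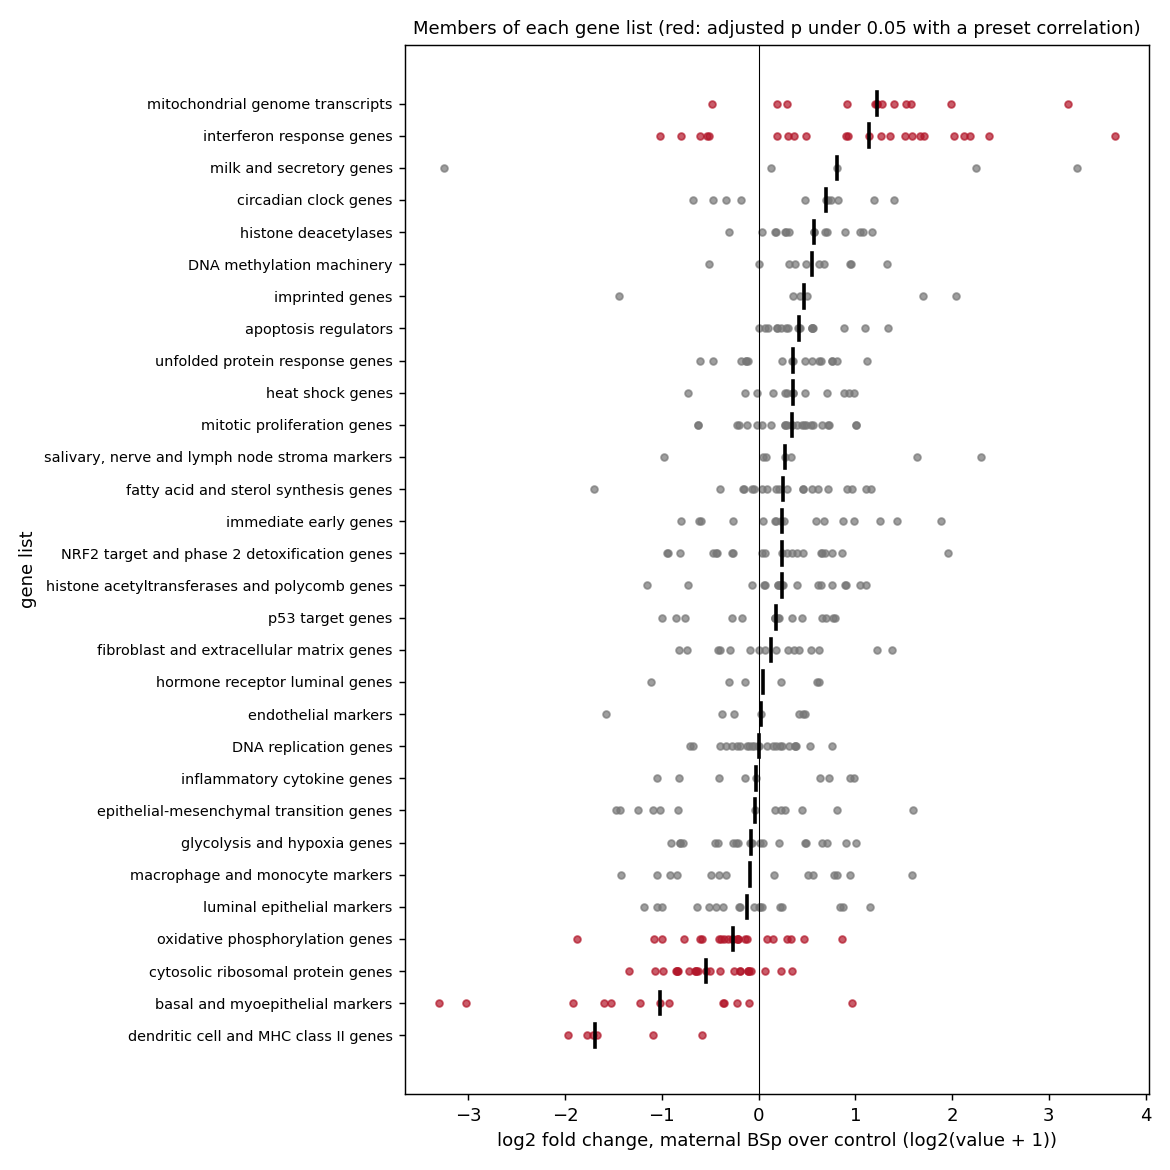
Log2 fold change of maternal BSp over control for the members of the 30 tested lists, 1 point per gene, with a bar at each median and red for lists with a camera adjusted p under 0.05. The medians run from -1.69 for dendritic and MHC class II genes to 1.23 for mitochondrial transcripts.

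NRF2 target and phase 2 detoxification genes, the response most tied to sulforaphane, did not pass as a list (camera adjusted p 0.754). Of 21 tested members 13 were higher and 8 lower (11 higher with upper quartile scaling), and 1 passed when adjusted over the list alone. Beside Gclm, the other members with the smallest p were lower: Pgd had a log2 fold change of -0.94 and the peroxiredoxin Prdx1 -0.81. Nqo1 measured 16.4 ± 2.32 in control and 28.2 ± 13.5 in maternal BSp, Txnrd1 45.6 ± 0.497 and 79.6 ± 20.4, and Hmox1 58.1 ± 9.73 and 122 ± 136, the last with 278 in maternal BSp replicate 2. Of the phase 1 and aryl hydrocarbon receptor list 4 genes were tested, too few for a list test, and Tiparp, Por and Ahr had log2 fold changes of 0.99, -0.66 and 0.59.

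Genes of the epigenetic machinery, studied as targets of sulforaphane, were mostly higher without passing. In the DNA methylation list 9 of 10 members were higher (adjusted p 0.19), 8 with upper quartile scaling, led by the demethylase Tet2 at 13.7 ± 6.12 and 34.5 ± 4.32, Dnmt3a at 26.8 ± 5.91 and 54.5 ± 18.99, and the methyl-DNA reader Mbd2 with a log2 fold change of 0.95. Dnmt1 measured 199 ± 7.12 and 265 ± 71.7. Among histone deacetylases 14 of 15 were higher (adjusted p 0.164), 11 with upper quartile scaling. Sirt1, Hdac5 and Sirt2 had log2 fold changes of 1.17, 0.71 and 0.68, while Hdac1, Hdac2 and Hdac3 had 0.32 (SE 0.49), 0.57 (SE 0.35) and 0.27 (SE 0.33), where Hdac1 turned lower with array weights and Hdac3 with the length and GC trend removed. In the acetyltransferase and polycomb list 16 of 19 were higher (adjusted p 0.482), 11 with upper quartile scaling, with Ep300 at 0.90, Kat6b at 1.11 and Suz12 at 0.76, and Ezh2 at 0.07 (SE 0.37), which turned lower with each of the other scalings.

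Of the 27 genes fixed in advance 23 were tested, and 20 were higher, 17 with upper quartile scaling. None passed over all genes tested, and 1, Gclm, passed when adjusted over the list alone (limma adjusted p 0.034). The proliferation marker Mki67 measured 222 ± 17.3 and 453 ± 97.1. Myc and Ccnd1 had log2 fold changes of 0.75 (SE 0.49) and 0.93 (SE 0.69), and the tumour suppressors Trp53, Rb1 and Brca1 0.41, 0.37 and 0.71. Cdkn1a and Cdkn2a had -0.86 (SE 0.72) and 0.10 (SE 0.42), where Cdkn2a turned lower with upper quartile or median-of-ratios scaling, and Erbb2 0.43 (SE 0.38). The luminal keratin Krt8 had -0.44 (SE 0.44) and the basal keratin Krt14 -1.92 (SE 1.09). Dnmt3b, Tert, Esr1 and Pgr lay below the filter, with Dnmt3b between 4 and 5.38 in each library and Pgr at 0 in both controls and at most 0.131 in maternal BSp.

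Lists of growth and stress responses did not pass. Mitotic genes were higher in 18 of 24 members (adjusted p 0.482), 16 with upper quartile scaling, with Foxm1 at a log2 fold change of 1.00 and Aurkb at 0.72. DNA replication genes were split 12 and 12 (adjusted p 0.482), with 7 higher under upper quartile scaling, and Pole was at 0.76, Tk1 at -0.68 and Mcm5 at -0.71. All 18 apoptosis regulators were higher, 13 with upper quartile scaling (adjusted p 0.19), with Casp8 at 1.34, Tnfrsf10b at 0.88 and Mcl1 at 0.57. Of the p53 targets (adjusted p 0.737) Phlda3 was at -0.997, Mdm2 at 0.77 and Plk2 at 0.69. Unfolded protein genes (adjusted p 0.624) were led by Dnajb9 at 1.12, Pdia4 at 0.81 and Hspa5 at 0.76, and heat shock genes (0.482) by Hsph1 at 0.99, Hspa8 at 0.94 and Hspa1b at 0.88. Immediate early genes (0.625) had Klf6 at 1.43, Nr4a1 at 1.89 and Junb at -0.80, clock genes (0.482) Cry1 at 1.19, Per1 at 1.40 and Nr1d2 at 0.82. For lipid synthesis (0.548) Elovl5 was at 0.91 and Acaca at 1.11, and for glycolysis and hypoxia (0.19) Hk1 at 1.01, Slc16a3 at -0.81 and Eno1 at -0.91, a list that was called lower without maternal BSp replicate 1 (0.0393). In the imprinted list (0.562) Grb10 was at -1.44 and H19 at 2.04 (SE 1.11). H19 read 9 and 9.34 in the controls and 57.1, 172 and 6.26 in maternal BSp replicates 1, 2 and 3, so the groups overlapped. Gnas passed when adjusted over the imprinted list alone. Members of other lists without a call also passed over their list alone. These were 2 of the milk list and 1 of the salivary, nerve and lymph node list. Kitl, the 1 tested gene of the neutrophil and mast cell list, had an unadjusted limma p of 0.015. Over a list of 1 gene there is no adjustment, and its limma adjusted p over all genes tested was 0.407.

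Cell type markers did not pass beyond the basal list and the dendritic and MHC class II list with all 5 libraries. Luminal markers (adjusted p 0.19) had Ehf at 0.85, Krt7 at -1.05 and Aldh1a3 at -0.997, and the hormone receptor list (0.625) Ly6a at -1.11, Xbp1 at 0.62 and Areg at 0.60. Macrophage genes (0.482) went both ways, with the secreted Spp1 at 1.59 and complement C1qa and C1qb at -1.42 and -1.05. Endothelial markers (0.482) had Flt1 at -1.58, Eng at 0.48 and Cdh5 at 0.46, the fibroblast list (0.802) Pdgfra at 1.23, Dcn at 1.38 and Col5a1 at -0.82, the mesenchymal transition list (0.184) Tgfbi at -1.47, Cdh2 at -1.44 and Mmp14 at -1.25, and the cytokine list (0.594) Il1rn at -0.82, Cxcl5 at -1.05 and Lcn2 at 0.98. The fibroblast list was called higher without control replicate 1 (adjusted p 0.0494) and lower without control replicate 2 (0.0208). The mesenchymal transition list was called lower without control replicate 2 (0.01) or maternal BSp replicate 2 (0.0371). In the milk list (0.824) the members diverged, with Ltf low, Muc15 at 2.25 and Csn3 at 1111 in maternal BSp replicate 3 against 2.94 to 18.8 elsewhere. The salivary, nerve and lymph node list (0.727) had Sox10 at 2.30, Pmp22 at 0.27 and Amy1 at 1.64. The direction of the camera test, which compares a list with all other genes, was lower while the median log2 fold change of the list was above 0 for NRF2 targets (0.24), p53 targets (0.18), the fibroblast list (0.12), the hormone receptor list (0.04), endothelial markers (0.03) and DNA replication genes (0.0024). The mean of the cytokine list was 0.09 and its median -0.03, the mean of the endothelial list -0.12 and that of the hormone receptor list -0.02.

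Markers of other tissues varied between single libraries of a group. The salivary gland genes Smr3a and Bpifa2, chosen after their values were seen, and Amy1 read 92, 278 and 96 in control replicate 1 and 1032, 604 and 478 in maternal BSp replicate 1, and at most 8.78 in the other 3 libraries. Among lists with fewer than 5 tested members, the adipocyte genes Pnpla2, Cebpa and Fabp4 had log2 fold changes of 1.12, 0.67 and 0.89, and the haemoglobins Hbb-bs, Hba-a1 and Hba-a2 -2.04, -1.89 and -0.90. These rest on maternal BSp replicate 2, at 0.108, 0.269 and 0.0538, and turned to 0.085, 0.64 and 0.81 without it, while maternal BSp replicate 3 was the highest library, at 393, 680 and 65.2. Lck, Sbsn, Kitl and Tnni2 were the only tested members of the T and NK cell, skin, neutrophil and mast cell, and muscle lists, at -0.15, -0.52, 1.45 and -0.66. B cell genes reached the filter in no case: Cd79a read 12.2 in maternal BSp replicate 1 and at most 1.44 elsewhere. The brown fat gene Ucp1 read 6 in control replicate 1 and at most 1.31 elsewhere.

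Maternal BSp replicate 3 stood apart in a stretch of distal chromosome 6, chosen after its values were seen. In a window of 15 neighbouring genes, from 142387221 to 146833529, the median log2 difference of this library from the mean of the other libraries was 3.68, where the windows of this library had a median of -0.04 and an SD of 0.36. The highest windows of the other libraries lay between 0.69 and 1.40. In the wider region from 136.8 to 149.6 Mb, set by its high windows in this library, 26 of 37 tested genes were highest in this library. Others there were not raised, such as Ccdc91, Ipo8 and Pthlh, with log2 differences of 0.11, 0.066 and -1.95. Fgfr1op2 and Med21 read 2614 and 2640 in this library and at most 152 and 144 in the others.

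**Figure D4:**
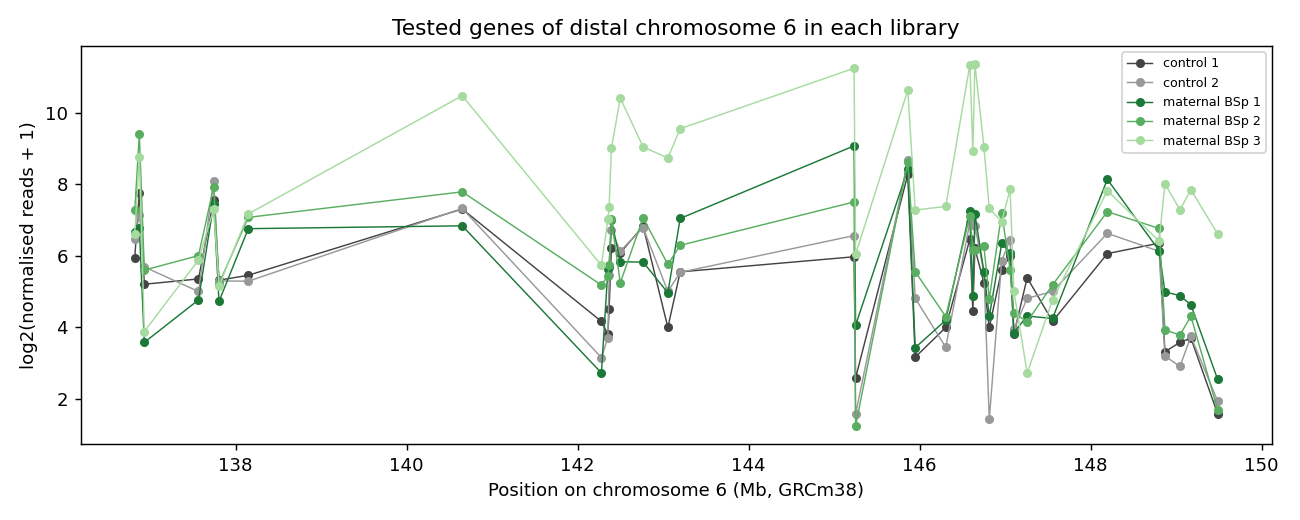
Normalised reads of the 37 tested genes from 136.8 to 149.6 Mb of chromosome 6 (GRCm38) on a log2(value + 1) axis, with 1 line per library and points at the gene midpoints. Maternal BSp replicate 3 is highest for 26 of the 37 genes.

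The authors' deposited table lists 1739 genes for control against BSp with an unadjusted p of up to 0.05, of which 875 were higher in BSp, 706 higher in control and 158 had no fold. For comparison with the authors' deposited table, 5% of all 38918 features is 1946. Only 19906 of these features had a read in these libraries. A feature without a read cannot differ between the groups, so 1946 is too high for a like comparison. Among these 1739 genes of the authors' deposited table, 619 had a mean under 10 in the normalised values and 155 had 0 reads in both controls. Of the 1736 genes of the authors' deposited table found in the normalised table, 1117 were tested here, 670 had an unadjusted p under 0.05 by limma and 0 an adjusted p under 0.05. Log2 ratios of the group means (each + 1) of the authors' deposited table correlated with the fold changes here at r = 0.998 across genes, which are not independent replicates. The authors' own fold ratios were not used for this. The group means of the authors' deposited table come from these same libraries and equalled the means of the normalised values within 1% for 1736 genes. This overlap is therefore not independent evidence.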

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

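The tests with thinned reads, with the length and GC trend removed, with totals without mitochondrial and rRNA-like genes, without the 2 libraries with salivary gene reads and with other DESeq2 filtering were chosen after seeing the data, and the rest were fixed in advance. limma called 0 genes, with 1101 at an unadjusted p under 0.05, and kept 0 under other filters, pseudocounts, scalings and the robust prior, and under edgeR (971 unadjusted). DESeq2 called 87 genes with default filtering, 100 with filtering set for 0.05 and 87 with none, and limma with array weights called 699. The array weights leaned on maternal BSp replicate 1, at 2.97 against 0.34 and 0.46 for maternal BSp replicates 2 and 3. Where a control is left out, the lone control is assumed to vary like the maternal BSp libraries. Leaving out each library gave 0 to 1 genes, the 1 without maternal BSp replicate 3. Without the 2 libraries with salivary gene reads 0 were called and 123 had an unadjusted p under 0.05, with 3 libraries left. Of the 24 genes named by smallest p, array weights called 24 and DESeq2 17. Of the fixed genes, array weights called 3 and DESeq2 1. Closeness of libraries had p = 0.7 (one-sided exact permutation test) with its sign reversed in the 1000 genes of highest variance. Ratios of the group means of the authors' deposited table had the same direction as here in 100% of 1117 and of 1736 genes. Those means come from the same values, so this is no independent check. In the simulated data 4.41% of genes changed by 1 on the log2 scale were recovered at the spread of these libraries, and 94.8% at a dispersion of 0.01 with the same depth, so the spread limits what a missing call can show. Except where an alternative uses fewer libraries or genes, the cause was not tested.

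The 6 list calls became 0 with an estimated correlation and 0 with fry (smallest adjusted p 0.82 and 0.32). In the other alternatives 3 to 6 of these 6 kept their call, the 3 without control replicate 2. The basal list was called in all alternatives but these 2. The interferon call was lost without control replicate 1 (adjusted p 0.551), with a mean of at least 50 (0.233) and without the 2 libraries with salivary gene reads (0.977). The ribosomal call was lost without control replicate 2 (0.0542) or maternal BSp replicate 2 (0.276), with quantile normalisation (0.0536) and with the length and GC trend removed (0.261). The oxidative phosphorylation call was lost in those same settings, at 0.0934, 0.216, 0.0536 and 0.356. The mitochondrial call was lost without control replicate 2 (0.0934) or maternal BSp replicate 1 (0.284) or 3 (0.352), with no filter (0.314) and without the 2 libraries with salivary gene reads (0.108), and the MHC class II call with no filter (0.154). Calls were gained for the mesenchymal transition list without control replicate 2 (0.01) or maternal BSp replicate 2 (0.0371) and for glycolysis without maternal BSp replicate 1 (0.0393), all lower, and for the fibroblast list without either control, in opposite directions.

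The following lists were not called as reported and changed direction in some alternatives, with the adjusted p given for each. Fry tests a list against no change and not against other genes, so its sign answers another question. With fry the sign was opposite for NRF2 targets (0.922), macrophage markers (0.965) and the fibroblast, p53 target, cytokine, hormone receptor and DNA replication lists (0.937 each), which is not a changed direction of the same comparison. NRF2 targets reversed with quantile normalisation (0.95), the length and GC trend removed (0.708) and without the 2 libraries with salivary gene reads (0.999), with 0.566 to 0.939 when each library was left out. The fibroblast list reversed with no filter (0.975), upper quartile (0.897), median-of-ratios (0.968) and quantile scaling (0.777), array weights (0.82), edgeR (0.92), DESeq2 (0.958) and without the 2 libraries with salivary gene reads (0.0993). Leaving out each library gave it 0.0208 to 0.525, with a call for lower values without control replicate 2 (0.0208) and for higher values without control replicate 1 (0.0494, median log2 fold change 0.67). p53 targets reversed with the length and GC trend removed (0.874) and without the 2 libraries with salivary gene reads (0.86), with 0.326 to 0.939 when each library was left out. Macrophage markers reversed with the length and GC trend removed (0.947), with 0.11 to 0.982 on leaving out each library, and the cytokine list with the trend removed (0.991), with 0.29 to 0.98. Hormone receptor genes reversed with array weights (0.82), with 0.314 to 0.98 on leaving out each library, and milk genes with array weights (0.986), with 0.646 to 0.98. Endothelial markers reversed with no filter (0.884), and immediate early and unfolded protein genes with a mean of at least 50 (0.781 and 0.978). Leaving out each library gave unfolded protein genes 0.177 to 0.939, lipid synthesis genes 0.177 to 0.916 and the salivary, nerve and lymph node list 0.0548 to 0.559.

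Single genes that changed direction had these log2 fold changes. Ezh2 was -0.16 with upper quartile, -0.12 with median-of-ratios and -0.0034 with quantile scaling, -0.19 with array weights, -0.12 with edgeR, -0.15 with DESeq2 and -0.23 with the length and GC trend removed, and -0.16 to 0.25 on leaving out each library. Cdkn2a was -0.13 with upper quartile and -0.083 with median-of-ratios scaling and -0.21 without the 2 libraries with salivary gene reads, with a leave-one-out range of -0.21 to 0.38. With the length and GC trend removed Rb1 was -0.15 (leave-one-out -0.064 to 1.04) and Hdac3 -0.028. Hdac1 was -0.12 with array weights (leave-one-out -0.11 to 0.63), and Eng -0.21 with thinned reads. Without the 2 libraries with salivary gene reads Areg was -0.12, Col5a1 0.18 (leave-one-out -1.95 to 0.32) and Sbsn 0.32 (leave-one-out -1.57 to 0.64). With edgeR and DESeq2, Hba-a1 was 0.43 and 0.41 (leave-one-out -3.90 to 0.64), Hba-a2 0.17 and 0.11 (-2.18 to 0.81), Hbb-bs 0.38 and 0.35 (-4.15 to 0.085) and Pmp22 -0.18 and -0.22 (-0.71 to 1.25). Further leave-one-out ranges were -1.48 to 4.76 for Amy1, -0.0896 to 1.02 for Cdh5, -0.047 to 2.81 for Dcn, -0.32 to 2.10 for Fabp4, -0.44 to 1.07 for Hmox1, -1.65 to 1.35 for Lck and -1.26 to 0.42 for Tnni2.

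Control and maternal BSp libraries share only 2 replicate numbers, 1 and 2 by description and 2 and 3 by title, and nothing in the labels says that they mark a litter, batch or day. Deviations of same-numbered libraries correlated at 0.0937 and -0.0923 by description number and at 0.0923 and 0.16 by title number. With 2 controls, their deviations from the control mean are mirror images. Each maternal BSp library therefore correlated with the 2 controls at the same size and with opposite sign. These values do not settle whether same-numbered libraries belong together. With the replicate number as a block limma called 23 genes, 5 of the 24 named genes, and 0 genes with the title number as a block. Maternal BSp replicate 3 has no control of its number by description, and replicate 1 has none by title. A library alone in its block adds nothing to the group comparison. The median log2 fold change of all tested genes, 0.30 by description and 0.26 by title, was thus that without the library concerned. The fold changes of single genes under a block are likewise those without that library. Under the block by description number the mitochondrial call was lost (adjusted p 0.186), and NRF2 targets (0.871), lipid synthesis (0.893), fibroblast (0.248), milk (0.893), p53 target (0.893) and unfolded protein genes (0.893) reversed, as did Lck (0.054), Sbsn (0.64) and Tnni2 (0.42 on the log2 scale). Under the block by title number the mitochondrial call was lost as well (0.112), the mesenchymal transition list was called (0.0433), and the salivary, nerve and lymph node list (0.469), Amy1 (-0.25), Cdkn2a (-0.21) and Rb1 (-0.055) reversed.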

Other observations

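The tests of explanations in this part, the scan along chromosomes and leaving out the 2 libraries with salivary gene reads were chosen after the results were seen, while leaving out single libraries and the estimated correlation were fixed in advance. The tumours also differed in genes of other tissues and cell types, library by library. Control replicate 1 and maternal BSp replicate 1 held reads of the salivary genes Smr3a, Bpifa2 and Amy1, with Bpifa2 at 278 and 604 and at 0 in the other 3 libraries. Maternal BSp replicate 1 also held the most B cell reads, with Cd79a at 12.2 and Pax5 at 6.02, where Cd79a was at most 1.44 and Pax5 at 0 in the others. Maternal BSp replicate 3 held milk protein reads, with Csn3 at 1111, Csn1s1 at 29.5 and Wap at 7.94, while the casein Csn2 was at 0 there. The same library had the lowest basal keratins, with Krt14 at 42.9 against 504 and 822 in the other maternal BSp libraries. Control replicate 2 had its highest window of 15 neighbouring genes on chromosome 17, from 33996017 to 34269419, a stretch of the MHC. Its median log2 difference from the other libraries was 0.94. The window holds H2-DMa, H2-DMb1 and H2-Ab1 of the dendritic and MHC class II list, so it and that list are not separate observations.

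Genes of the ribosome and of oxidative phosphorylation were lower in maternal BSp, in libraries that also differed in depth and in read classes, but not in maternal BSp replicate 3, which lay above control replicate 1 in both lists (0.50 against 0.05 and 0.30 against 0.04), and both calls were lost with an estimated correlation (adjusted p 0.82 each) and with fry (0.742 each). With all libraries thinned to the smallest total the ribosomal list kept a median of -0.54, with a camera adjusted p of 9.68e-05 at the preset correlation. Thinning covers counting error only, as values had already been scaled to 1 total. Other differences that go with depth therefore stay open. Transcript length and GC content may account for the oxidative phosphorylation list, whose median went from -0.26 to -0.076 once their trend was removed, and in part for the ribosomal list, which went from -0.54 to -0.33 and stays open. The median of all tested genes moved the other way, from 0.21 to 0.013. Against all genes both lists therefore moved further than these values show. The rRNA-like share was 10.03 times as high in the controls, as a library preparation that differed between the groups could give. Such a difference would coincide with the diet groups, so the design cannot tell it apart from diet. An effect of the maternal diet was not tested apart from these.

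Interferon response genes were higher in maternal BSp as a list, a call lost with an estimated correlation (adjusted p 0.82) and without the 2 libraries with salivary gene reads (0.977), and the list median of maternal BSp replicate 3 (-0.016) lay no higher than that of control replicate 2 (0.0011). Length or GC content as the whole cause is argued against, since the list had a median of 1.04 once the trend was removed, against 1.14 before. The median of all tested genes went from 0.21 to 0.013, so against all genes the list did not fall. With thinned reads the list had a camera adjusted p of 0.00254 at the preset correlation. That argues against counting error from unequal depth as the whole cause, while other differences that go with depth stay open. More myeloid cells are argued against, since 20 macrophage, monocyte, dendritic and MHC class II markers had a median log2 fold change of -0.54 (SD 1.05). That pool holds the 6 dendritic and MHC class II genes already called lower as a list (median -1.69). The 14 macrophage and monocyte markers alone were split 7 and 7, with a median of -0.09. Without control replicate 1, where the spread comes from maternal BSp alone and the lone control is assumed to vary like it, the median was 0.54 and the adjusted p 0.551, so low interferon genes in that 1 tumour may account for part of it. A difference in library preparation and an effect of the maternal diet were not tested and stay open.

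On distal chromosome 6 a block of neighbouring genes was high in maternal BSp replicate 3. Length and GC content are argued against, since the highest window had a median log2 difference of 3.66 once their trend was removed, against 3.68 before. A copy gain of the region in this tumour stays open, since DNA was not analysed here and the count of 26 of 37 genes highest in this library decides nothing in a region chosen for its high genes. Within it the log2 differences had quartiles of 0.80 and 3.69, with Pthlh at -1.95, and no biological explanation tied to diet was tested with 1 library.

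The 5 libraries can be split into 2 and 3 in 10 ways, too few for a share under 0.05. The real split gave 1101 genes with an unadjusted p under 0.05 and the highest other split, maternal BSp replicates 1 and 2 against the rest, gave 1270. Thus 2 of 10 splits, the real one included, gave 1101 or more. At a limma adjusted p under 0.05 the real split gave 0 genes. The split of control replicate 1 and maternal BSp replicate 1 against the rest gave 3.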
